A study of Mus musculus with 12 samples.

How the data were processed

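RNA sequencing was done on 12 samples of mouse tibialis anterior muscle in 3 groups of 4, Sham, KPC and KPC_UA. Per the labels' protocols, KPC cells were injected into the surgically exposed pancreas of C57BL/6J mice, muscles were frozen in liquid nitrogen, total RNA was extracted with an RNeasy kit, and RNA integrity was checked before sequencing. Integrity values per sample were not used here. Per the submitters' processing notes, bcl2fastq 2.17, featureCounts and Subread 1.5.2 were used with the GRCm38 genome. The aligner, the annotation, the use of strand in counting and the test for differential expression are not given in the sources used here.

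The authors deposited 3 tables, one for each pair of groups, with a normalised signal per gene and library, log2 fold changes, p-values and adjusted p-values, per the file headers. The tables held 13578 genes for KPC against Sham, 13557 for KPC_UA against KPC and 13583 for KPC_UA against Sham, and the lowest sum of reads of a listed gene over its 8 libraries was 81, so that genes with few reads could not be tested. Within each column the normalised values were whole multiples of a single step, and dividing by it gave whole reads for 100% of values (tolerance 0.01 reads). Each library gave the same reads in both tables that hold it, for 100% of shared genes. The values are therefore read counts divided by a size factor per library, set separately in each table, and each comparison was tested within its own table. DESeq2 1.42.0 with default settings on the recovered reads gave the authors' deposited log2 fold changes for 100% of genes in each table, and their p-values for 100%, 99.985% and 99.993%.

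Gene symbols were assigned by gene identifier from a reference list, and the deposited name was used for the few identifiers that it lacked. Of the names in each table, 13 were missing and 19 had been turned into dates by a spreadsheet, and 19 were restored from the gene identifiers. Coordinates and exonic lengths come from GENCODE M21, which uses GRCm38, and are counted from 1. Values of Acot1 are uncertain because its paralog Acot2 lies beside it.

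The recovered reads in listed genes ranged from 22.3 to 32.0 M per library. No samples were left out, and no columns of other samples were present. The root mean square difference in log2 values between a library and the other members of its group had a median of 0.352 to 1.04 over the 12 libraries.

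The test for genes was limma 3.58.1 in R 4.3.3, two-sided, with a variance trend and robust estimation, on log2(value + 1) of genes with a mean normalised value of at least 10 over the 8 libraries of a table, with Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low genes. The gene lists, the tests and the rule for naming genes were fixed before the data were examined. A set of 35 gene lists was written for muscle atrophy, metabolism, fibre types, signalling and the cell types a dissected muscle can hold, and 33 had at least 3 tested members in each comparison. Lists were tested with limma's camera at a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation, fry and an exact permutation test of list means stand beside it. With 4 samples against 4, the smallest p of the exact permutation test is 0.0286.

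Genes named in the text follow a rule. It takes the 5 largest called increases and decreases with a mean value of at least 50 and no overlap between groups, skipping unnamed and predicted genes and pseudogenes, up to 3 members with the smallest p of each list described, and Fbxo32, Trim63, Foxo1, Gadd45a, Cdkn1a, Atf4, Igf1, Mstn and Smox in each comparison. Acot2 was added as the paralog of Acot1, and liver transcripts and genes of counts of 5 or fewer were chosen after their values were seen.

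The relation of the effects of tumour and ursolic acid was computed across genes tested in both tables, with all 4 KPC libraries and with these split so that no library entered both effects, also with each library left out, of which the Sham and KPC_UA libraries were added after the result was seen. It was set beside 1000 simulated sets of unchanged groups, made by multiplying each library's deviation from its group mean by a random normal number, and simulated ranges hold the central 95% of these. Shares of genes with opposite signs, and after their values were seen the median changes of these genes, were set beside 100 sets and overlaps of DESeq2 calls beside 25 sets made in the same way.

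Alternatives were pseudocounts of 0.5 and 5, no filter on low values, a mean of at least 50, rescaling by TMM, quantile normalisation, limma without trend and robust estimation, edgeR 4.0.16 quasi-likelihood tests and DESeq2 on the recovered reads, edgeR over all 12 libraries, the authors' adjusted p-values, a threshold of 1 on the log2 fold change, the replicate number as a block, and each library left out in turn. Chosen after seeing the data were removal of the trend with transcript length, the length slope of a library as a covariate, leaving out the library of each group that read long transcripts less, array weights, and the exact permutation test of lists.

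The tests for genes, limma, edgeR and DESeq2, were tried on simulated data with 200 changed genes and the spread of these libraries. For KPC against Sham, over 13578 genes, limma found 24% of 2-fold and 89% of 4-fold changes, and 5 of its 118 calls were unchanged genes. For KPC_UA against KPC, over 13557 genes, it found 26% and 99%, and 7 of 132 calls were unchanged genes. For KPC_UA against Sham, over 13583 genes, it found 85% and 100%, and 8 of 193 calls were unchanged genes. DESeq2 made 29, 46 and 23 calls on unchanged genes among 171, 201 and 212 in these comparisons. Camera at the preset correlation called 100% of 20 raised lists in each comparison, and 1, 0 and 1 of 200 unchanged lists. Camera with an estimated correlation, fry and the exact permutation test were not tried on simulated data. The simulated spread was independent between genes, whereas deviations of the real libraries are shared by many genes. Plots were drawn with matplotlib 3.10.9.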

Results

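Gene expression was measured by RNA sequencing in the mouse tibialis anterior, a fast-twitch muscle of the lower hindlimb. The 12 libraries fell into 3 groups of 4 samples, all from C57BL/6J mice. Sham samples came from tumour-free mice on standard chow. KPC samples came from mice on standard chow that carried tumours grown from KPC cells, a mouse pancreatic cancer line placed in the pancreas. KPC_UA samples came from mice with the same tumours whose chow contained ursolic acid, a triterpenoid found in fruit peel. The labels list separate samples in each group but do not state that each came from a different mouse, so the p-values measure only the spread between these samples.

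Reads in the listed genes numbered 23.8, 29.4, 23.8 and 24.7 M in Sham replicates 1 to 4, 22.3, 22.8, 23.7 and 32.0 M in the KPC replicates, and 25.6, 27.7, 28.3 and 26.4 M in the KPC_UA replicates. The KPC samples differed most from each other. A principal component that held 60.3% of the variance placed KPC replicates 1 and 4 at 112 and 46.6, and KPC replicates 3 and 2 at 11.5 and -7.66. Sham samples lay between -30.6 and -25.2 on it, and KPC_UA samples between -23.4 and -1.24. The median standard error of a log2 fold change was 0.27 in KPC against Sham, 0.27 in KPC_UA against KPC and 0.17 in KPC_UA against Sham.

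KPC and Sham muscle were compared to ask which transcripts differ in the muscle of tumour-bearing mice. Transcripts of fatty acid use and of a muscle ubiquitin ligase were higher in KPC muscle, and transcripts of collagens and of a muscle growth factor were lower. Fbxo32, which encodes the ubiquitin ligase atrogin-1, rose from a normalised read count of 9817 ± 1839 to 83273 ± 69490 (SD, n = 4 per group; log2 fold change 2.71, SE 0.51, adjusted p = 0.0432 by limma). Pdk4, a kinase that restrains glucose oxidation, rose from 8008 ± 3232 to 86478 ± 82750 (SD, n = 4 per group; log2 fold change 3.09, SE 0.54, adjusted p = 0.0380 by limma). Col1a1, a chain of type I collagen, fell from 2734 ± 506 to 692 ± 334 (SD, n = 4 per group; log2 fold change -2.09, SE 0.32, adjusted p = 0.0323 by limma). Igf1, the insulin-like growth factor, fell from 223 ± 30.7 to 69.0 ± 21.02 (SD, n = 4 per group; log2 fold change -1.71, SE 0.24, adjusted p = 0.0255 by limma).

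**Figure D1:**
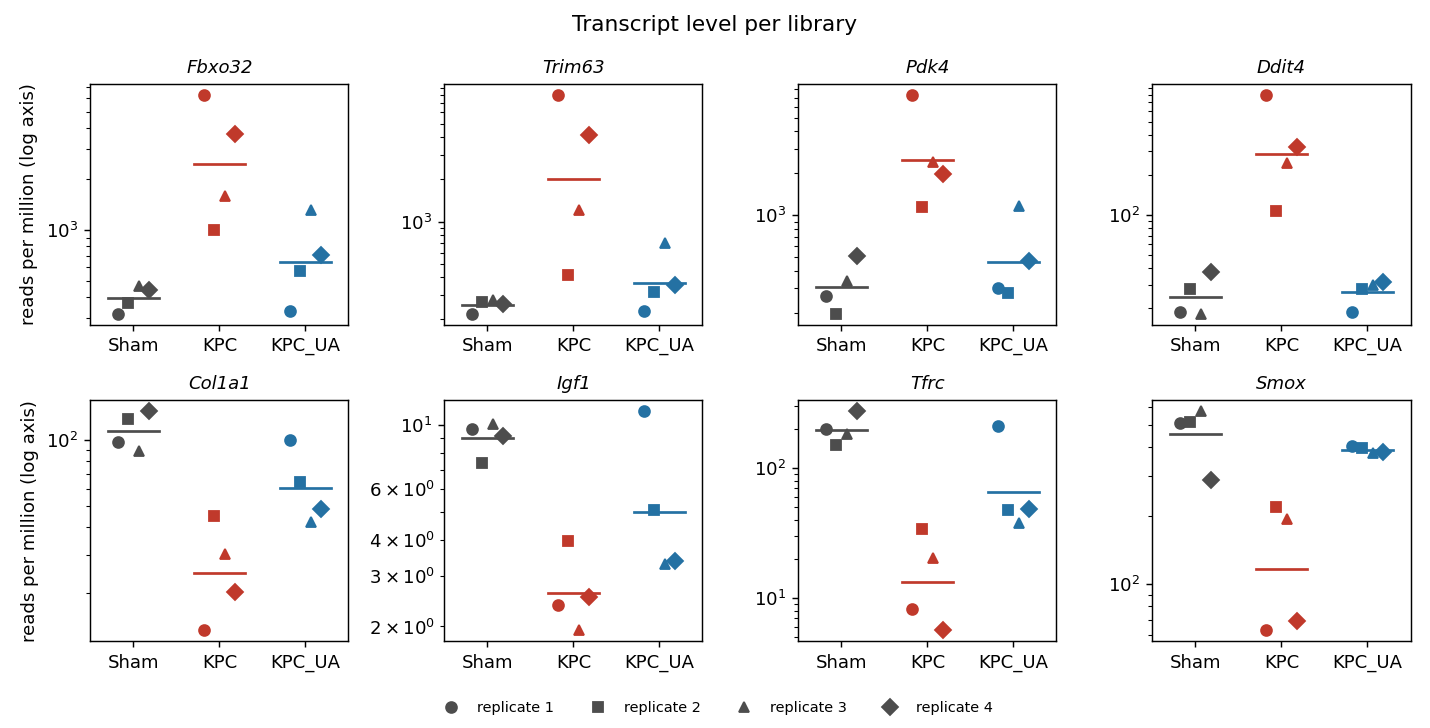
CPM values (reads scaled to a common library total) of 8 genes in each of the 12 libraries, on a log axis, with a symbol for each replicate and a line at the geometric mean of each group. Fbxo32 lay between 319 and 468 in Sham, between 1002 and 6307 in KPC and between 332 and 1317 in KPC_UA, and Tfrc between 150.3 and 275 in Sham, between 5.63 and 33.9 in KPC and between 38.0 and 212 in KPC_UA.

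Of 13542 genes tested, 160 passed limma's threshold, 48 higher and 112 lower in KPC, and 151 of them changed by more than 1 on the log2 scale. At an unadjusted p under 0.05 there were 3312 genes. In 2588 genes (19.1%) the 4 KPC values did not overlap the 4 Sham values, where chance gives 2.86%.

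Under the rule for naming genes (mean value of at least 50, no overlap between groups), the largest called increases were in Acot1, Il6ra, Ddit4, Pdk4 and Rassf4. Acot1, a cytosolic acyl-CoA thioesterase (chromosome 12, 84009490 to 84018371, GRCm38), was 33.0-fold higher, with a log2 fold change of 5.04 (SE 0.90, adjusted p = 0.0380 by limma). Its value is uncertain because its neighbour Acot2 (chromosome 12, 83987861 to 83993873) is nearly identical in sequence and the counting could split their reads. Acot2 had a log2 fold change of 2.79 (adjusted p = 0.0466 by limma). Il6ra, the interleukin-6 receptor (chromosome 3, 89864059 to 89913196), had a log2 fold change of 3.79 (SE 0.74, adjusted p = 0.0454 by limma). Ddit4, a stress-induced inhibitor of mTORC1 (chromosome 10, 59949669 to 59951834), went from 623 ± 214 to 9899 ± 8871 (SD, n = 4 per group), a log2 fold change of 3.63 (SE 0.54, adjusted p = 0.0321 by limma). Pdk4 lies on chromosome 6 (5483351 to 5496309). Rassf4 (chromosome 6, 116633008 to 116673952) had a log2 fold change of 2.89 (SE 0.45, adjusted p = 0.0337 by limma).

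Under the same rule, the largest called decreases were in Tfrc, Foxo6, Arnt2, Map3k7cl and Irx3os. Tfrc, the transferrin receptor that takes up iron (chromosome 16, 32608920 to 32632794), fell from 4953 ± 1223 to 434 ± 321 (SD, n = 4 per group; log2 fold change -3.82, SE 0.49, adjusted p = 0.0255 by limma). Foxo6, a forkhead transcription factor (chromosome 4, 120267079 to 120287349), had a log2 fold change of -3.61 (SE 0.66, adjusted p = 0.0398 by limma). For Arnt2, a basic helix-loop-helix transcription factor (chromosome 7, 84246278 to 84410176), the log2 fold change was -3.51 (SE 0.62, adjusted p = 0.0380 by limma). For Map3k7cl (chromosome 16, 87553330 to 87595336) it was -3.43 (SE 0.44, adjusted p = 0.0255 by limma). Irx3os, a transcript named for the strand opposite Irx3 (chromosome 8, 91800415 to 91807539), had a log2 fold change of -2.98 (SE 0.53, adjusted p = 0.0380 by limma). Its value is uncertain because strand use in the counting is not given in the sources used here.

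Camera called 3 lists of muscle protein breakdown higher in KPC muscle, but limma's fry did not (adjusted p = 0.0623 for the ubiquitin ligases, 0.203 for the proteasome and 0.106 for autophagy). The 19 ubiquitin ligases and FOXO factors of muscle atrophy rose by a mean of 0.95 on the log2 scale (camera adjusted p = 0.000165, adjusted p = 0.485 with an estimated correlation). Among them 1 gene rose when adjusted over all genes and 7 when adjusted over the list alone. Trim63, which encodes the ubiquitin ligase MuRF1, had a log2 fold change of 3.05 (adjusted p = 0.0809 by limma), and Foxo3 1.69 (adjusted p = 0.0780 by limma). The 31 proteasome subunits rose by a mean of 0.71 (camera adjusted p = 9.82e-07, adjusted p = 0.518 with an estimated correlation). All 31 had positive fold changes, but 0 passed limma's threshold, both over all genes and adjusted over the list alone. Psma5 had a log2 fold change of 1.10 (adjusted p = 0.125 by limma). The proteasome mean lay 1.45 and 1.33 above the Sham mean in KPC replicates 1 and 4, and at -0.0497 and 0.0943 from it in KPC replicates 2 and 3. The 23 genes of autophagy and the lysosome rose by a mean of 0.62 (camera adjusted p = 0.000165, adjusted p = 0.493 with an estimated correlation), with 0 called over all genes or adjusted over the list alone. Without KPC replicate 1 the mean was 0.46 for the proteasome and 0.41 for autophagy and the lysosome. Map1lc3b, an autophagosome membrane protein, had a log2 fold change of 1.15 (adjusted p = 0.104 by limma).

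Fatty acid oxidation genes also rose, by a mean of 1.10 over 24 genes (camera adjusted p = 2.47e-09, adjusted p = 0.485 with an estimated correlation). All 24 had positive fold changes, 4 rose when adjusted over all genes and 14 when adjusted over the list alone. Ucp3, a mitochondrial carrier induced in fasting muscle, rose from 2890 ± 825 to 9720 ± 3668 (SD, n = 4 per group; log2 fold change 1.71, adjusted p = 0.0380 by limma). The 17 glucocorticoid response genes rose by a mean of 1.70 (camera adjusted p = 6.06e-07, adjusted p = 0.485 with an estimated correlation). Over all genes 2 of them rose, Ddit4 and Glul, and adjusted over the list alone 14 rose and 1 fell. Glul, glutamine synthetase, had a log2 fold change of 2.49 (adjusted p = 0.0461 by limma). The 17 genes of ribosome biogenesis and translation rose by a mean of 0.57 (camera adjusted p = 5.72e-05, adjusted p = 0.493 with an estimated correlation), with 0 called over all genes and 9 higher and 1 lower adjusted over the list alone. The elongation factor Eef2 had a log2 fold change of 0.60 (adjusted p = 0.0835 by limma).

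Collagens and other extracellular matrix genes fell. The mean of 24 genes fell by 1.29 on the log2 scale (camera adjusted p = 7.32e-11, adjusted p = 0.424 with an estimated correlation), with 10 lower over all genes and 18 lower adjusted over the list alone. Col6a2 had a log2 fold change of -2.40 (adjusted p = 0.0255 by limma) and Col1a2 -1.99 (adjusted p = 0.0255 by limma). Camera also called markers of cells that make such matrix. The 7 tendon markers fell by a mean of 2.43 (camera adjusted p = 6.06e-07, adjusted p = 0.485 with an estimated correlation), with 2 lower over all genes and 7 lower adjusted over the list alone. Tnmd, a membrane protein of tendon cells, had a log2 fold change of -2.92 (adjusted p = 0.0371 by limma) and Thbs4 -1.79 (adjusted p = 0.0380 by limma). The 12 fibroblast and fibro-adipogenic progenitor markers fell by a mean of 0.93 (camera adjusted p = 6.07e-05, adjusted p = 0.485 with an estimated correlation), with 1 lower over all genes, Mfap5 (log2 fold change -1.63, adjusted p = 0.0371 by limma), and 7 lower adjusted over the list alone. The 9 adipocyte markers fell by a mean of 1.02 (camera adjusted p = 0.0209, adjusted p = 0.485 with an estimated correlation), although 4 had positive fold changes. With genes of a mean of at least 50 the list mean was 0.0656 (adjusted p = 0.780 by camera), the opposite direction. Of these 3 fell over all genes, and 2 rose and 5 fell adjusted over the list alone. Those 3 were Plin1 at -3.02, Cfd at -1.90 and Cidec at -1.74 on the log2 scale (adjusted p = 0.0255, 0.0413 and 0.0454 by limma), which encode fat droplet proteins and an adipose-derived protease.

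The 14 genes of the list of IL-6, STAT3 and acute phase rose by a mean of 0.88 (camera adjusted p = 0.000789, adjusted p = 0.424 with an estimated correlation), with 3 higher over all genes and 6 higher and 1 lower adjusted over the list alone. The 3 were Il6ra, Il4ra (log2 fold change 1.40, adjusted p = 0.0373 by limma) and Osmr (1.25, adjusted p = 0.0380 by limma). The 23 interferon response genes fell by a mean of 0.69 (camera adjusted p = 0.000317, adjusted p = 0.493 with an estimated correlation), with 0 called over all genes or adjusted over the list alone. Without KPC replicate 1 their mean was -0.35 (adjusted p = 0.00425 by camera). The 6 erythroid markers, which mark blood in the tissue, rose by a mean of 1.90 (camera adjusted p = 0.000292, adjusted p = 0.485 with an estimated correlation), with 0 called over all genes and 6 higher adjusted over the list alone. Slc4a1, the red cell anion exchanger, had a log2 fold change of 2.63 (adjusted p = 0.0646 by limma).

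Other named regulators of muscle mass were mixed. Gadd45a, a stress-induced gene linked to muscle denervation, rose by 2.19 on the log2 scale (adjusted p = 0.0454 by limma). Cdkn1a had a log2 fold change of 2.70 (adjusted p = 0.113 by limma), Foxo1 1.84 (adjusted p = 0.0901 by limma), Mstn 1.25 (adjusted p = 0.156 by limma) and Atf4 1.02 (adjusted p = 0.127 by limma). Smox, spermine oxidase, had a log2 fold change of -1.91 (adjusted p = 0.0601 by limma).

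**Figure D2:**
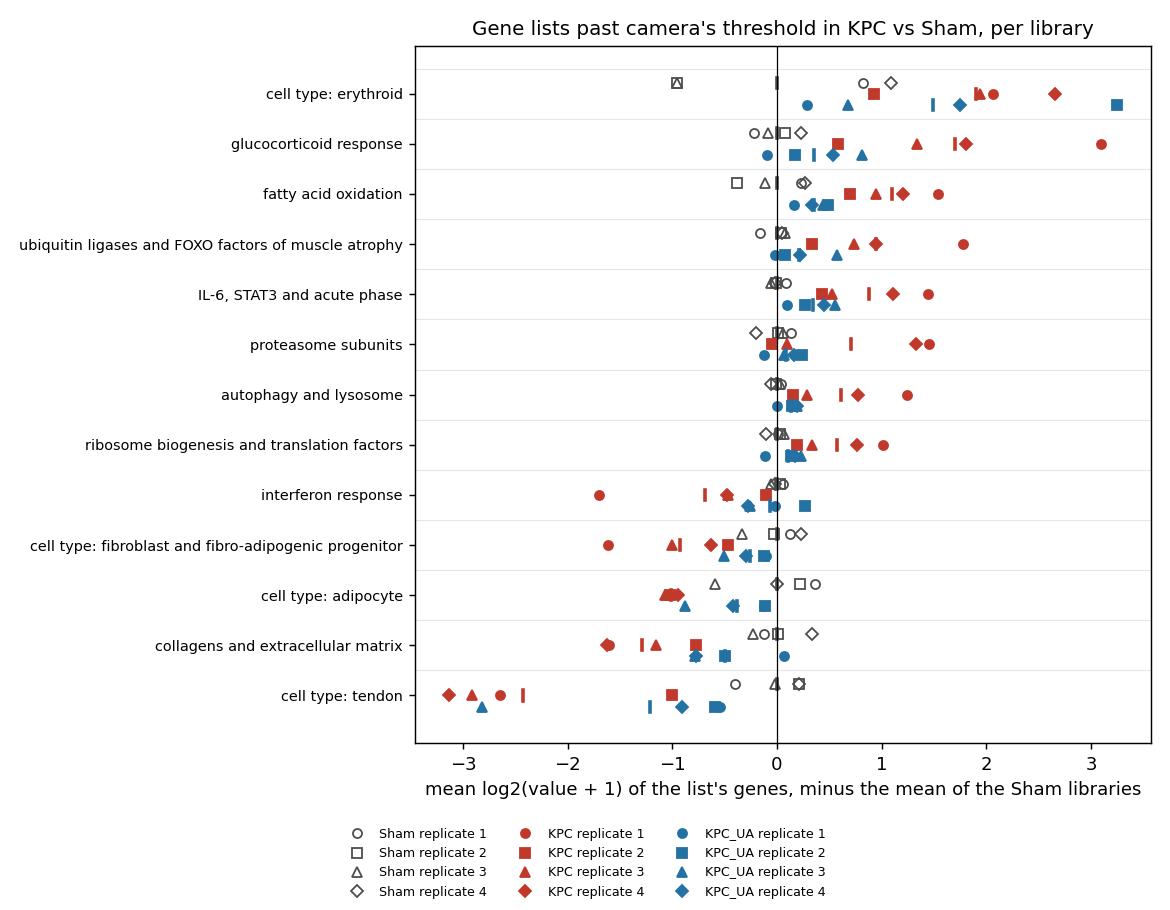
Mean log2(value + 1) of the genes of each list past camera's threshold in KPC against Sham, for each library, minus the mean of the Sham libraries, with a symbol for each replicate and a bar at each group mean. Proteasome subunits lay at 1.45 and 1.33 in KPC replicates 1 and 4 and at -0.0497 and 0.0943 in KPC replicates 2 and 3.

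In all, 13 of 33 lists passed camera's threshold, 8 higher and 5 lower, and 0 with an estimated correlation. The directional test fry called 4 of them, the collagen, fatty acid oxidation, tendon and IL-6 lists (adjusted p = 0.0164, 0.0498, 0.0284 and 0.0164 by limma's fry). By edgeR 196 genes passed and by DESeq2 1595 (916 higher, 679 lower), which is also the count in the authors' deposited table. The limma count of 160 became 0 without KPC replicate 3, without KPC replicate 4 or without any of Sham replicates 1, 2, 3 and 4, 395 without KPC replicate 1 and 1352 without KPC replicate 2. It was also 0 with the library of each group that read long transcripts less left out, here Sham replicate 1 and KPC replicate 4. The adipocyte list lost its camera call without KPC replicate 2 (mean -1.01, about as with it, adjusted p = 0.0773 by camera) or Sham replicate 1 (mean -0.68, adjusted p = 0.149 by camera), and without Sham replicate 1 and KPC replicate 4 together (mean -0.70, adjusted p = 0.171 by camera).

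KPC_UA and KPC muscle were compared to ask whether ursolic acid in the chow altered the muscle of tumour-bearing mice. By camera, lists of muscle breakdown and fatty acid use were lower in KPC_UA and the collagen list was higher, but 0 lists passed with an estimated correlation (smallest adjusted p = 0.545). Ddit4 was at 688 ± 155 in KPC_UA and 10138 ± 9065 in KPC (SD, n = 4 per group; log2 fold change -3.50, SE 0.53, adjusted p = 0.382 by limma). Fbxo32 was at 18728 ± 10800 and 85299 ± 71020 (SD, n = 4 per group; log2 fold change -1.97, SE 0.60, adjusted p = 0.382 by limma). Of 13522 genes, limma called 0, with 1714 at an unadjusted p under 0.05 and a smallest adjusted p of 0.382. By edgeR 0 genes passed, by edgeR over all 12 libraries 2, by DESeq2 100 (27 higher, 73 lower) and in the authors' deposited adjusted p-values 99 (26 higher, 73 lower).

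Among the genes named by rule, those past DESeq2's threshold included lower Ddit4 (adjusted p = 1.23e-09 by DESeq2), lower Angptl4, a secreted inhibitor of lipoprotein lipase (log2 fold change -2.61 by limma, adjusted p = 4.75e-05 by DESeq2), lower Cldn5, a tight junction protein of endothelium (-1.28 by limma, adjusted p = 0.00740 by DESeq2), and lower Ucp3 (-1.52 by limma, adjusted p = 0.0131 by DESeq2). Fbxo32 and Trim63 had adjusted p = 0.0270 and 0.0325 by DESeq2, with a limma log2 fold change of -2.51 for Trim63. Higher in KPC_UA were Plin1 (1.88 by limma, adjusted p = 0.0182 by DESeq2) and Smox (1.70 by limma, adjusted p = 0.0302 by DESeq2). Smox was at 9979 ± 263 in KPC_UA and 3556 ± 2086 in KPC (SD, n = 4 per group), and its 4 values in each group did not overlap. The same held for 1071 of the 13522 genes tested (7.92%), where chance gives 2.86%. The limma adjusted p was 0.382 for each of the genes named here.

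Camera called 13 of 33 lists, 6 higher and 7 lower in KPC_UA, and 0 with an estimated correlation. Over all genes 0 members of these lists were called by limma, with the unadjusted and DESeq2 counts as given for the comparison. Proteasome subunits fell by a mean of 0.63 over 31 genes (camera adjusted p = 4.60e-07, adjusted p = 0.577 with an estimated correlation), with 0 called adjusted over the list alone. The ubiquitin ligase and FOXO list fell by 0.74 (camera adjusted p = 0.000300, adjusted p = 0.545 with an estimated correlation) and autophagy and lysosome genes fell by 0.49 (camera adjusted p = 0.000364, adjusted p = 0.545 with an estimated correlation), each with 0 called adjusted over the list alone. Glucocorticoid response genes fell by 1.35 (camera adjusted p = 1.88e-06, adjusted p = 0.545 with an estimated correlation), with 3 lower adjusted over the list alone. In that list Cebpd, a transcription factor induced by glucocorticoids, had a log2 fold change of -3.12 (adjusted p = 0.382 by limma). Fatty acid oxidation genes fell by 0.75 (camera adjusted p = 1.88e-06, adjusted p = 0.545 with an estimated correlation), with 6 lower adjusted over the list alone. Ribosome biogenesis and translation genes fell by 0.48 (camera adjusted p = 7.38e-05, adjusted p = 0.545 with an estimated correlation), and IL-6, STAT3 and acute phase genes fell by 0.62 (camera adjusted p = 0.0181, adjusted p = 0.545 with an estimated correlation). Both had 0 called adjusted over the list alone. In the former, Myc was at -1.31 (adjusted p = 0.382 by limma). Without KPC replicate 1 the mean was -0.38 for the proteasome, -0.47 for the ubiquitin ligase list, -0.28 for autophagy and the lysosome, -0.89 for the glucocorticoid list and -0.41 for the IL-6 list.

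In KPC_UA against KPC, the 24 genes of collagens and the extracellular matrix rose by a mean of 0.79 (camera adjusted p = 7.93e-07, adjusted p = 0.545 with an estimated correlation), with 8 higher adjusted over the list alone. Lum, a collagen-binding proteoglycan, had a log2 fold change of 1.26 (adjusted p = 0.382 by limma). Fibroblast markers rose by 0.66 (camera adjusted p = 0.000201, adjusted p = 0.545 with an estimated correlation), with 2 higher adjusted over the list alone, and tendon markers rose by 1.21 (camera adjusted p = 0.00521, adjusted p = 0.545 with an estimated correlation), with 0 called adjusted over the list alone. Interferon response genes rose by 0.63 (camera adjusted p = 1.83e-05, adjusted p = 0.545 with an estimated correlation) and oxidative phosphorylation genes rose by 0.28 (camera adjusted p = 0.000318, adjusted p = 0.633 with an estimated correlation), each with 0 called adjusted over the list alone. Glycolysis and glycogen genes rose by 0.24 (camera adjusted p = 0.0105, adjusted p = 0.545 with an estimated correlation), with 2 higher and 1 lower adjusted over the list alone. Without KPC replicate 1 the mean was 0.43 for fibroblast markers, 0.29 for the interferon response and 0.14 for oxidative phosphorylation, which was at 0.17 without KPC_UA replicate 2. Tendon markers were at 1.83 without KPC replicate 2, and lost their camera call with the library of each group that read long transcripts less left out, here KPC_UA replicate 2 and KPC replicate 4 (mean 0.90, adjusted p = 0.0739 by camera). The glycolytic enzymes Tpi1 and Ldha had log2 fold changes of 0.84 and 0.81 (adjusted p = 0.382 by limma for both).

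Without KPC replicate 2, limma called 3 genes lower in KPC_UA, and without any other of the 8 libraries 0. They were Ddit4 (log2 fold change -3.98, adjusted p = 0.0196 by limma), Depp1 (-4.27, 0.0316) and the predicted gene Gm10603 (-2.67, 0.0196), the last pair named after their values were seen. Ddit4 and Gm10603 were also those called by edgeR over all 12 libraries. The IL-6 list lost its camera call without KPC_UA replicate 1 (mean -0.52, adjusted p = 0.0631 by camera) and without the pair of libraries that read long transcripts less (mean -0.51, adjusted p = 0.0553 by camera).

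KPC_UA and Sham muscle were compared to ask how muscle of treated tumour-bearing mice differed from that of tumour-free mice. By camera, the collagen and tendon lists were lower and the fatty acid oxidation and IL-6 lists higher in KPC_UA, but 0 lists passed with an estimated correlation (smallest adjusted p = 0.489). Foxo6 was at 150.4 ± 50.9 in KPC_UA and 296 ± 32.5 in Sham (SD, n = 4 per group; log2 fold change -1.03, SE 0.21, adjusted p = 0.230 by limma). Il4ra was at 247 ± 70.9 and 132 ± 19.9 (SD, n = 4 per group; log2 fold change 0.87, SE 0.19, adjusted p = 0.233 by limma). Of 13567 genes limma called 0, with 1077 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0967. By edgeR 0 genes passed, also over all 12 libraries, and 94 (52 higher, 42 lower) by DESeq2 and in the authors' deposited table.

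Camera called 15 of 33 lists in this comparison, 12 higher and 3 lower, and 0 with an estimated correlation. The lower lists were the collagens at a mean of -0.50 (camera adjusted p = 2.86e-09, adjusted p = 0.489 with an estimated correlation), tendon markers at -1.21 (camera adjusted p = 4.27e-05, adjusted p = 0.489 with an estimated correlation; mean -0.68 without KPC_UA replicate 3) and fibroblast markers at -0.26 (camera adjusted p = 0.00213, adjusted p = 0.499 with an estimated correlation). Adjusted over the list alone, 9 collagen and 2 tendon genes fell, and 1 fibroblast marker rose and 1 fell, with 0 called over all genes in each. Col1a2 had a log2 fold change of -0.83 (adjusted p = 0.302 by limma) and Tnmd -1.72 (adjusted p = 0.361 by limma). Ly6a, the stem cell antigen Sca-1, was the fibroblast marker that rose over the list alone, at 0.81 (adjusted p = 0.230 by limma).

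Fatty acid oxidation genes rose by a mean of 0.36 (camera adjusted p = 4.31e-07, adjusted p = 0.489 with an estimated correlation; mean 0.23 without Sham replicate 2), with 0 called over all genes and 2 higher adjusted over the list alone. Ucp2 had a log2 fold change of 0.73 (adjusted p = 0.2498 by limma). IL-6, STAT3 and acute phase genes rose by 0.34 (camera adjusted p = 0.000396, adjusted p = 0.489 with an estimated correlation), with 0 called over all genes and 4 higher adjusted over the list alone. Osmr had a log2 fold change of 1.004 (adjusted p = 0.302 by limma). Erythroid markers rose by 1.49 (camera adjusted p = 0.000663, adjusted p = 0.489 with an estimated correlation), macrophage markers by 0.31 (camera adjusted p = 0.00248, adjusted p = 0.489 with an estimated correlation) and the 3 measured neutrophil markers by 1.09 (camera adjusted p = 0.00860, adjusted p = 0.489 with an estimated correlation). Over all genes 0 of these markers were called, and adjusted over the list alone 2 neutrophil markers were higher. In KPC against Sham, the mean was 0.31 for macrophage and 1.44 for 4 neutrophil markers (adjusted p = 0.133 and 0.0877 by camera). In KPC_UA against KPC these means were -0.00871 and -0.187, so the markers were not particular to the treated muscle. S100a9, a neutrophil calcium-binding protein, had a log2 fold change of 1.93 (adjusted p = 0.230 by limma), against 2.74 in KPC over Sham (adjusted p = 0.0494 by limma).

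Camera also called lists of muscle breakdown and stress higher than in Sham, and limma's fry called 0 lists in this comparison. Autophagy and lysosome genes rose by 0.13 (camera adjusted p = 0.00250, adjusted p = 0.489 with an estimated correlation), ATF4 and integrated stress response genes by 0.16 (camera adjusted p = 0.00732, adjusted p = 0.489 with an estimated correlation) and glucocorticoid response genes by 0.36 (camera adjusted p = 0.00617, adjusted p = 0.599 with an estimated correlation). The ubiquitin ligase and FOXO list rose by 0.21 (camera adjusted p = 0.0125, adjusted p = 0.599 with an estimated correlation), ribosome and translation genes by 0.10 (camera adjusted p = 0.0125, adjusted p = 0.599 with an estimated correlation), proteasome subunits by 0.0850 (camera adjusted p = 0.0125, adjusted p = 0.856 with an estimated correlation) and oxidative phosphorylation genes by 0.10 (camera adjusted p = 0.0473, adjusted p = 0.856 with an estimated correlation). Over all genes 0 members of these lists were called. Adjusted over the list alone, 3 glucocorticoid response genes rose and 1 fell, 1 autophagy gene rose, and 0 genes of the other 5 lists were called. Fbxo32 had a log2 fold change of 0.74 (adjusted p = 0.635 by limma), Trim63 0.54 (adjusted p = 0.677 by limma) and Ddit4 0.15 (adjusted p = 0.963 by limma).

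The limma count rose from 0 to 3 without KPC_UA replicate 1 and to 4 without Sham replicate 1. Without the former, Tfrc and Scd1 were lower and Ly6c1 higher, and without the latter, Mdga1 and Fras1 were lower and Ier5 and Gm26917 higher. Apart from Tfrc, these genes were named after their values were seen. Some camera calls were lost with 1 library left out, in part with little change in the mean log2 fold change. The oxidative phosphorylation list (mean 0.10) lost its call without KPC_UA replicates 1, 2 or 4 (means 0.10, -0.00954 and 0.0934, adjusted p = 0.0994, 0.981 and 0.102 by camera) or Sham replicates 2, 3 or 4 (means 0.00265, 0.0690 and 0.11, adjusted p = 0.931, 0.224 and 0.0507 by camera). Its mean was 0.21 without KPC_UA replicate 3 and 0.22 without Sham replicate 1. With all libraries it lost its call among genes of a mean of at least 50 (adjusted p = 0.0555 by camera) and with the replicate number as a block (adjusted p = 0.0527 by camera). The ribosome list (mean 0.10) lost its call without KPC_UA replicates 2, 3 or 4 or Sham replicate 4 (means 0.0946, 0.0626, 0.0811 and 0.0705, adjusted p = 0.0503, 0.122, 0.0652 and 0.0987 by camera), and its mean was 0.18 without KPC_UA replicate 1. The proteasome list (mean 0.0850) lost its call without KPC_UA replicates 2 or 4 or Sham replicate 4 (means 0.0322, 0.0602 and 0.0216, adjusted p = 0.435, 0.113 and 0.565 by camera), and its mean was 0.16 without KPC_UA replicate 1 and 0.13 without Sham replicate 1. For the ubiquitin ligase list (mean 0.21) this was so without KPC_UA replicate 3 or Sham replicate 1 (means 0.0952 and 0.16, adjusted p = 0.174 and 0.177 by camera), for the ATF4 list (mean 0.16) without KPC_UA replicate 2 (mean 0.14, adjusted p = 0.0548 by camera) and for the glucocorticoid list (mean 0.36) without Sham replicate 1 (mean 0.29, adjusted p = 0.0697 by camera). The glucocorticoid mean was 0.21 without KPC_UA replicate 3.

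The effect of ursolic acid was set against the effect of the tumour across the 13375 genes tested in both, because the design asks whether the treated muscle moved toward the tumour-free state. Across genes, which are not independent replicates, the log2 fold changes of KPC_UA minus KPC and of KPC minus Sham had a correlation of -0.918, a covariance of -0.349 and a slope of -0.732. Both effects contain the 4 KPC libraries with opposite sign, so unchanged groups also give negative values. Simulated unchanged groups gave a mean correlation of -0.684 (95% range -0.968 to -0.0587) and a mean covariance of -0.106 (-0.422 to -0.00139). With the KPC libraries split so that the effects shared none, the mean covariance over the 6 splits was -0.242, below the simulated range of -0.218 to 0.178, and the mean correlation was -0.576, inside the range of -0.630 to 0.687. Repeated simulations without KPC replicate 1 gave lower bounds of the split covariance between -0.236 and -0.213. Such variation is about as large as the margin here, so a value just past its range is not firmly below it. With each of the 12 libraries left out in turn, the split covariance lay below its range in 6 settings. It lay inside without KPC replicates 1, 3 or 4 (-0.1019, -0.286 and -0.184), Sham replicate 2 (-0.2433, where the range began at -0.2444) or KPC_UA replicates 1 or 2 (-0.217 and -0.229). It was -0.397 without KPC replicate 2, where the split correlation (-0.594) also lay below its range (from -0.543). Without KPC replicate 1 the split correlation was -0.354 and the covariance with shared libraries -0.185, against -0.547 without KPC replicate 2.

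Of the 160 genes called in KPC against Sham, 151 were tested in KPC_UA against KPC and all 151 had the opposite sign there, 125 of them at an unadjusted p under 0.05 and 0 past limma's threshold. These genes were chosen with the same KPC libraries, and in simulated unchanged groups a mean of 91.5% of the 160 genes with the smallest p had the opposite sign (95% range 55.6 to 100%). With the KPC libraries split and 160 genes chosen anew from each pair by the smallest p, called or not, a mean of 95.6% of those tested in both had the opposite sign in the comparison with the other pair (86.3 to 98.7% over the splits). This lies inside the range of 5.29 to 96.4% of simulated unchanged groups split in the same way. The 48 called genes that were higher in KPC had a median log2 fold change of 1.74 in KPC minus Sham, -1.07 in KPC_UA minus KPC and 0.70 in KPC_UA minus Sham. For the 103 lower genes tested in both, the medians of KPC minus Sham and of KPC_UA minus KPC were -1.95 and 1.15. The median of KPC_UA minus Sham was -0.75 over all 112 lower genes. These medians share libraries with the choice of the genes. For the 160 genes of smallest p in simulated unchanged groups, the 95% range of the median of KPC_UA minus KPC was -1.22 to -0.0264 for higher and 0.0170 to 1.20 for lower genes, and that of KPC_UA minus Sham was -0.0478 to 0.64 and -0.72 to 0.0641. The observed medians of KPC_UA minus Sham lay just outside these ranges. Those of KPC minus Sham also lay outside theirs (0.344 to 1.34 and -1.36 to -0.327). The simulated genes thus had smaller changes to begin with, so these ranges are not a like comparison. With the KPC libraries split, the median of KPC_UA minus KPC was -1.52 to -0.31 for higher and 0.39 to 1.52 for lower genes over the splits. The means over the splits, -1.04 and 1.045, lay inside the simulated ranges of -1.14 to 0.79 and -0.79 to 1.21.

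The 3 comparisons share libraries in pairs, and by limma 0 genes were called in more than 1 of them, since limma called 0 genes in the comparisons with KPC_UA. By DESeq2, 68 genes were higher in KPC against Sham and lower in KPC_UA against KPC, where independent lists of these sizes share 5.07, and 24 were lower and then higher, against 1.31. In 25 simulated sets of unchanged groups that shared the KPC libraries, 6 gave such an overlap above 0, with a median of 0, a mean of 58.0 and a highest value of 1204. With the KPC libraries split so that the comparisons shared none, the overlap was 16 to 607 genes over the 6 splits, against 2.03 to 156 for independent lists. Also by DESeq2, 39 genes were higher and 29 lower in both KPC and KPC_UA against Sham, where independent lists share 3.43 and 2.09. Of 25 simulated sets, 1 gave an overlap above 0, of 4 genes. With the Sham libraries split, the overlap was 2 to 20 genes, against 0.0803 to 1.73. The values for independent lists treat genes as independent, whereas deviations of these libraries are shared by many genes. No simulated unchanged groups were split in this way, so the split overlaps do not show whether they exceed what unchanged groups give.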

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

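Of the tests in this part, the read depth of KPC replicates 1 and 4, the comparison of the length trend between groups and the shares of erythroid reads were chosen after the result was seen. A library lay far from the other 3 of its group in 14 of 273 groups of values examined, where chance flags about 1 in 20 groups, or 13.6. The score beside each is the gap to the nearest library over the whole range of the group.

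Read depth stood apart in Sham replicate 2 (29.4 M reads, score 0.839) and in KPC replicate 4 (32.0 M, score 0.854). Among gene lists, the mean log2 value of the ubiquitin ligase and FOXO list was low in Sham replicate 1 (10.9, others 11.1, score 0.847), that of the glycolysis list in Sham replicate 4 (14.97, others 15.13 to 15.15, score 0.932), and that of tendon markers in KPC_UA replicate 3 (4.46, others 6.37 to 6.73, score 0.841). Among genes in Sham, Foxo6 was high in replicate 1 (score 0.831), and Ldha (score 0.934) and Myog (score 0.967) were low in replicate 4. Mstn, which encodes myostatin, was high in KPC replicate 1 (log2 value 12.3, others 10.1 to 10.2, score 0.956). In KPC_UA replicate 1, Tfrc was high (12.35, others 9.93 to 10.3, score 0.842) and Psma5 (score 0.873) and Eef2 (score 0.941) were low, and Casq1, the calcium store protein of fast fibres, was high in replicate 2 (score 0.868).

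A pattern in the size of the response was that KPC replicates 1 and 4 lay above KPC replicates 2 and 3 in the ubiquitin ligase and FOXO list (mean log2 values of 12.8 and 11.98 against 11.4 and 11.8). This pattern was noticed in the data. KPC replicate 4 lay nearer to KPC replicate 3 than to KPC replicate 1, so the libraries do not form clear pairs. For KPC replicate 4, lower read depth is excluded as the cause, since it held 31.97 M reads, more than KPC replicate 2 or 3. KPC replicate 1 held the fewest reads of the 12 (22.31 M), but KPC replicate 2 held nearly as few (22.8 M). Their list means were 12.8 and 11.4, which argues against read depth as the cause in KPC replicate 1 as well. The trend with transcript length is also excluded as the whole cause: with it removed per library, the gap between the nearest libraries of the pairs kept 147% of its size (0.309 against 0.211). The labels give no group that parts these libraries, so no biological explanation was tested.

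Another pattern was a trend with transcript length in 1 library of each group, KPC replicate 4 (score 0.8291), Sham replicate 1 and KPC_UA replicate 2. Across genes, their deviation from the group mean correlated with exonic length at -0.465, -0.507 and -0.536, and with genes in 5 bins by length, the mean deviation of the longest bin minus that of the shortest was -0.53, -0.40 and -0.39 on the log2 scale. Deviations from a group mean sum to 0 within the group, so a low library in each group is in part built in. With deviations from the mean of all 12 libraries, the correlations were -0.289, -0.392 and -0.486 in these libraries. KPC_UA replicate 4 was also low by that measure, at -0.219. The trend lies within groups, so a comparison of the groups by that measure (smallest exact permutation p = 0.4571, two-sided) decides nothing about its source. Leaving out blood and mitochondrial transcripts, 37 of 11789 genes, moved the correlations of -0.465, -0.507 and -0.536 by at most 0.003 (the highest then was -0.468). So few genes could hardly do otherwise, so this decides nothing either. The share of reads in erythroid genes was the highest of the group in KPC replicate 4, Sham replicate 1 and KPC_UA replicate 2 (0.0436, 0.0140 and 0.0618%), though in Sham replicate 4 it was 0.0138%. The share in mitochondrial genes was the highest of the group in 0 of the libraries with the highest erythroid share. Sham replicate 4 had almost the erythroid share of Sham replicate 1 and a correlation of 0.376 by deviation from the group mean, which argues against blood in Sham. In KPC replicate 4 and KPC_UA replicate 2, erythroid genes held only 0.0436 and 0.0618% of reads, while the trend ran across 11789 genes. This argues against reads from blood as its direct source there. Differences in RNA integrity or library preparation stay open, and the sources used here give no value per library for them.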

How the results depend on the processing

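Of the alternatives in this part, DESeq2 and edgeR for the overlap, length correction, the length slope as a covariate, the libraries with fewer long-transcript reads left out, array weights and the exact test of lists were chosen after the result was seen, and the cause of each change given here was not tested, except that fewer genes or libraries enter some settings by construction. For the 160 genes called in KPC against Sham, the count was 87 at a mean of at least 50, 257 with quantile normalisation, 1595 with DESeq2 and with the authors' adjusted p, 1478 with edgeR over 12 libraries, 4907 with array weights, 0 with the length slope as a covariate and 0 without the libraries that read long transcripts less. Leaving out each library in turn gave 0 to 1352, and the other settings, apart from the replicate block, 150 to 220. For KPC_UA against KPC, where limma called 0 genes, the count was 100 with DESeq2, 99 with the authors' adjusted p, 2 with edgeR over 12 libraries, 2988 with array weights and 0 to 3 with each library left out. For KPC_UA against Sham, also at 0, it was 94 with DESeq2 and with the authors' adjusted p, 10 with the length trend removed, 732 with array weights, 6 with the length slope as a covariate, 4 without the libraries that read long transcripts less and 0 to 4 with each library left out.

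List counts of 13, 13 and 15 became 0 in each comparison with an estimated correlation and with the exact permutation test, and 4, 0 and 0 with fry. For the exact test a count of 0 was nearly fixed in advance. Its smallest p is 0.0286, so many of the 33 lists must reach it together before any passes adjustment. By that test 12, 3 and 3 lists had an unadjusted p under 0.05. With each library left out, the list counts by camera were 12 to 19, 13 to 14 and 12 to 16. The adipocyte list reversed in KPC against Sham at a mean of at least 50 (0.0656), where genes of low value leave it. In KPC_UA against Sham the oxidative phosphorylation list reversed without KPC_UA replicate 2 (-0.00954), with -0.00954 to 0.219 over all libraries left out in turn. Mstn in KPC_UA against Sham, at -0.0366, turned positive with edgeR (0.00738) and without KPC_UA replicates 1 (0.173) and 2 (0.0492) or Sham replicates 2 (0.0920) and 3 (0.0766), with -0.278 to 0.173 over all libraries left out in turn. The correlation of opposed effects was -0.576 with the KPC libraries split and -0.946 to -0.863 with each library left out. The overlap of calls, 0 by limma, was 160 genes by DESeq2 over both pairs of comparisons.

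With the replicate number as a block, 66 genes were called in KPC against Sham. Deviations from the group mean correlated between -0.265 and 0.135 for same-numbered samples. In most samples these deviations correlated best with a sample of another number, so the numbers do not pair the samples. Of named genes 1712 values kept their side of the threshold and direction, 40 gained a call, 167 lost it and 5 reversed, and of lists 510 kept theirs, 143 lost the call and 2 reversed. Read depth limits genes of low value most, and those with few reads were not in the tables.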

Other observations

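Of the tests in this part, the splits of the samples for gene counts of the comparisons with KPC_UA, the look at liver transcripts, the opposed effects without a Sham or KPC_UA library and the order of the libraries in splits with many genes were chosen after the result was seen, and the rules for reading the tests of the opposed effects were made stricter after their values were known.

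Camera did not call the lists of fast-fibre contraction, glycolysis and the nerve contact in KPC against Sham, and limma called 0 of their genes over all genes, with the unadjusted and DESeq2 counts as given for the comparison. Casq1 was at 22588 ± 15730 in KPC and 67623 ± 12240 in Sham (SD, n = 4 per group; log2 fold change -1.87, adjusted p = 0.0784 by limma), and 5 genes of the list of fast-fibre sarcomere and calcium handling fell when adjusted over the list alone. The same number fell in the glycolysis and glycogen list, in which Ldha had a log2 fold change of -0.96 (adjusted p = 0.0858 by limma). In the list of denervation and the neuromuscular junction, 4 genes rose when adjusted over the list alone. Its members Chrna1, an acetylcholine receptor subunit, and Myog, a myogenic transcription factor, had log2 fold changes of 1.37 and 1.14 (adjusted p = 0.0821 and 0.0702 by limma), and Myog had 0.97 in KPC_UA against Sham (adjusted p = 0.332 by limma). The camera adjusted p of the 3 lists was 0.0711, 0.0723 and 0.345. The clock repressor Nr1d1 fell from 4445 ± 499 in Sham to 2258 ± 516 in KPC (SD, n = 4 per group; adjusted p = 0.0472 by limma) and had a log2 fold change of -0.69 in KPC_UA against Sham (adjusted p = 0.230 by limma).

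Liver transcripts appeared in Sham replicate 1. Alb gave 523 reads there, and at most 2 in the other Sham libraries and 11 in KPC replicate 3. Apoa1 gave 230 reads in that library and at most 3 in any other. The source of these reads was not tested, and the library is also the Sham library with fewer reads in long transcripts.

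The effect of ursolic acid ran opposite to that of the tumour. A hypothesis is that ursolic acid moved the muscle back toward the tumour-free state, and a technical explanation is the shared KPC libraries, which may create such a relation. With these split, the mean covariance was -0.242, below the range of simulated unchanged groups (-0.218 to 0.178), but the mean correlation was inside its range, so the test leaves this open. The margin is about as large as the variation of a simulated bound, which was -0.213 to -0.236 in repeated simulations without KPC replicate 1. Without KPC replicate 1 the split covariance shrank to -0.1019, inside a range about as wide as with all 4 libraries (-0.236 to 0.185). It was also inside without KPC replicate 3 (-0.286) and KPC replicate 4 (-0.184), where the ranges were wider (-0.388 to 0.405 and -0.479 to 0.412), and below the range without KPC replicate 2 (-0.397, range -0.299 to 0.320). With a Sham or KPC_UA library left out, it was inside without Sham replicate 2 (-0.2433) and KPC_UA replicates 1 and 2 (-0.217 and -0.229), so it passes its range by little. The covariance shrank most without KPC replicate 1. Whether it rests on this library alone stays open, since a value inside the range does not show that the relation is absent.

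Other splits of the same 8 libraries into 4 and 4 bear on whether chance can be excluded, and there are 35 such splits in each comparison. For the 160 genes called by limma in KPC against Sham, 1 of 35 splits, the real one, gave as many genes, and the highest of the others gave 0. This is the smallest share that 35 splits can give, so it argues against chance for that count but cannot exclude it. In 100 simulated sets of unchanged groups, limma called genes in 2, as many as 1665. For the 1595 genes called by DESeq2, 1 of 35 splits also gave as many, and the highest other gave 92. DESeq2 called genes in this comparison in 6 of 25 simulated sets. The highest count was 1256, below 1595, but 25 sets are too few to exclude chance there either. For the counts of 0 genes by limma in the comparisons with KPC_UA, all 35 splits reach 0 by construction (highest other 1 in both), so the splits decide nothing there. For DESeq2 in KPC_UA against KPC, 2 of 35 splits gave at least 100 genes and the highest other gave 307, and in KPC_UA against Sham 5 gave at least 94 and the highest other gave 388, so chance is not excluded for these. Splits that call several times the real count point to a structure of the samples. The split with 307 genes parts the 4 libraries lowest on the first principal component from the 4 highest, and that component comes from the same expression values. In KPC_UA against Sham, a split with 344 genes parts the 4 libraries with the highest correlations with transcript length from the 4 lowest. For all splits by length, these correlations use deviations from the mean of all 12 libraries. The split with 388 genes follows neither order exactly. Its sides differ by 0.321 in mean correlation with length, against 0.466 for the split with 344 genes, but a split with a difference of 0.414 gave 3 genes. The splits by length in KPC against Sham and KPC_UA against KPC gave 17 and 15 genes. Each of these splits by length also parts the libraries by the second principal component. No single order covers these counts. In 25 simulated sets of unchanged groups that kept the deviations of these libraries, DESeq2 called as many as 1256 genes in KPC against Sham, 2807 in KPC_UA against KPC and 932 in KPC_UA against Sham, with a median of 0 in each. Chance is not excluded for the lists either. In KPC against Sham 10 of 35 splits gave at least 13 lists (highest other 16), in KPC_UA against KPC 6 gave at least 13 (highest other 15), and in KPC_UA against Sham 4 gave at least 15 (highest other 18).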
